A study of Mus musculus with 2 samples.

How the data were processed

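Gene expression was measured in single mouse thymus cells from 5 sorted populations, each stained with its own hashtag antibody (TotalSeq-A) and pooled into a single Chromium Single Cell 3' v3 cDNA library with a matching hashtag library. Per the labels, the authors processed the reads with Cell Ranger 3.0 against mm10. The deposited matrix holds counts, as UMI counts per gene and cell barcode, whole numbers with no normalization, for 27998 genes and 8293 barcodes. The deposited hashtag table holds counts per barcode for each of the 5 hashtags and for tags that matched none; whether these are reads or UMIs is not given in the sources used here. The authors assigned each barcode to a population from the hashtags, by a rule that is not given in the sources used here, and left 345 barcodes (4.16%) unassigned. Filters on cells or genes before deposition are not given in the sources used here.

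The authors' assignment was used as deposited. It was checked against the hashtag counts: the most abundant hashtag was the assigned one in 100% of the 1412, 1182, 1205, 847 and 3302 assigned cells, by raw counts and after centred log-ratio scaling, and the median share of the assigned hashtag was 99.3%, 99.2%, 98.8%, 99.2% and 99.3%. Unassigned barcodes were left out of every comparison, since they belong to no population. Doublets with 1 hashtag cannot be seen in the hashtag counts and were not called; from the 313 unassigned barcodes that carry 2 hashtags (a second hashtag at 20% or more of the hashtag counts) their number was estimated at 110, or 1.39% of assigned cells. No clustering was done, since the sorts define the groups. Gene identifiers were matched to GENCODE M21, where 27645 of 27998 were found, and coordinates were taken from it.

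UMIs were summed over the cells of each population and scaled to 1000000 per population (CPM). The 5 comparisons were Flt3- Ly6d- HSA- over Flt3+ Ly6d- HSA-, Flt3+ HSA+ over Flt3+ Ly6d- HSA-, Flt3- Ly6d+ over Flt3- Ly6d- HSA-, Flt3- Ly6d+ over Flt3+ HSA+, and the control over the unweighted mean of the 4 gated sorts. Each population came from 1 sort, so cells are not replicates and no test between populations was run. A gene was counted when its ratio was at least 2, with at least 20 CPM and a UMI in at least 5% of cells in the higher population. A gene was counted as particular to a sort when it met this rule over each of the other 3 gated sorts. Ratios carry 95% intervals from the binomial split of the summed counts (for the control, from a log-normal approximation) and CPM values carry exact Poisson intervals; shares of cells carry exact Clopper-Pearson intervals. All of these cover counting error only. Where a gene had 0 UMIs in the lower population no ratio was given.

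Named genes were chosen by a rule: the 12 genes with the largest ratios in each direction among those past the size rule for the first 4 comparisons, 8 in each direction for the control, and at most 6 per sort for genes particular to it. Predicted genes, mitochondrial genes, ribosomal protein genes and clone names were counted but not named. Gate genes and members of the fixed lists could be named too. The 19 lists were gate genes, stem and progenitor regulators, T-lineage regulators, T-cell receptor and signalling components, Notch targets, homing and cytokine receptors, S phase genes, G2 and M phase genes, Myc-linked growth and nucleolar genes, immediate early and stress genes, and 9 lists of other cell types (granulocyte and monocyte, dendritic, B cell, NK and innate lymphoid, gamma delta T cell, mast cell and basophil, erythroid and megakaryocyte, later thymocyte and thymic epithelial markers). A member was measured at 5 CPM or more in either population, and members at least 1.5-fold apart were counted. The median log2 ratio of each list was ranked among 10000 random lists of genes matched in expression over 20 bins (seed 20). Some genes stand in several lists, such as Ccr9 and Gzmb. Some values of single list members are not reported here.

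Shares of cells with a UMI, marker shares and the score were computed after thinning each cell to 3000 UMIs at random, which left out 7, 6, 45, 21 and 52 cells that were too shallow. A cell was counted for another cell type when at least 2 markers of the list had a UMI. The score of a cell was the mean log value (scaled to 10000) of T-lineage regulators and receptor components minus that of stem and progenitor regulators.

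Rules, lists, comparisons and the alternatives that follow were fixed before the data were examined. These alternatives were edgeR TMM factors, DESeq2 size factors, totals without mitochondrial and ribosomal protein genes, equal weight for each cell, thinning to 3000 UMIs, cells with at least 1000 genes and under 10% mitochondrial UMIs, leaving out the 5% of cells with most UMIs, cells whose assigned hashtag was at least 80% of at least 20 hashtag counts, leaving out cells with 2 or more markers, at full depth, of granulocytes and monocytes, B cells, erythroid cells, mast cells or thymic epithelium, minimums of 5 and 100 CPM, no minimum share of cells, 3 markers in place of 2 for other cell types, thinning to 1500 UMIs or full depth, the score from regulators alone, and centred log-ratio scaling of hashtags. The cut of 20 Hbb-bt UMIs per cell was set after seeing the data. Also chosen after seeing the data were leaving out cells with 7 or more of the 14 granulocyte and monocyte markers, and keeping only cells without a G2 or M phase UMI among 3000. In the first of these settings, lists kept the members measured over all assigned cells. Some of these members then lay under 5 CPM in both populations.

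The size rule was tested on simulated data, Poisson counts around the pooled profile of each of the first 4 comparisons at its real totals, in which 200 genes were given a known ratio: in each comparison all 80 genes at 2.5-fold and all 80 at 4-fold were recovered, 0 of 40 at 1.5-fold passed, and no unchanged gene passed. The minimum share of cells was not part of this test. The simulated counts vary by Poisson error alone and hold no spread between cells or sorts. The simulation therefore checks the arithmetic of the rule and does not give its rate of false calls in these data. The TMM and DESeq2 factors of single populations lay within 0.044 of 0 on the log2 scale. A ratio moves by the difference between the factors of its populations. In the fourth comparison the TMM factors were 0.042 for Flt3- Ly6d+ and -0.044 for Flt3+ HSA+ cells. The tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.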

Results

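RNA was measured in single cells from the thymus of C57BL/6 mice carrying a yellow fluorescent reporter at Bcl11b, a regulator of T-lineage commitment. The cells were 4 sorted fractions of early thymic progenitors, the most immature T-cell precursors of the thymus, and 1 broader control sort of Kit+ cells. All 4 fractions were Kit+ CD25- Bcl11b- and negative for lineage markers. They were split by surface Flt3, a cytokine receptor of early progenitors, Ly6d, a surface antigen of lymphoid cells, and HSA, the CD24 antigen. Each sort carried its own hashtag, an antibody barcode, and all 5 went into 1 library. The authors assigned 1412 cells to the Flt3+ Ly6d- HSA- sort, 1182 to the Flt3+ HSA+ sort, 1205 to the Flt3- Ly6d- HSA- sort, 847 to the Flt3- Ly6d+ sort and 3302 to the control. The series text states that the sorts were made to profile populations that an earlier pseudotime ordering had pointed to.

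The sorts differed in depth, so their profiles were compared as UMI counts summed over cells and scaled to 1000000 per population (CPM). The summed totals were 24624463 UMIs in Flt3+ Ly6d- HSA- cells, 25619232 in Flt3+ HSA+ cells, 14018324 in Flt3- Ly6d- HSA- cells, 10616041 in Flt3- Ly6d+ cells and 57199129 in the control. Median UMIs per cell in the same order were 15478, 21152, 9860, 11404 and 16040, and median genes per cell were 3730, 4408, 2929, 3209 and 3851. Mitochondrial transcripts made up a median of 4.20%, 4.18%, 4.78%, 4.85% and 4.64% of UMIs. There was 1 sort of each kind, so no difference between sorts could be tested against the spread of repeated sorts. Counts of genes are therefore descriptions by a fixed size rule: at least 20 CPM and a UMI in at least 5% of cells in the higher population, and a ratio of at least 2. The 5% was counted at full depth, so deeper sorts meet it more easily. Intervals in parentheses are 95% intervals of CPM (Poisson), of ratios of counts, or of shares of cells (exact Clopper-Pearson). These cover counting error only. The flagged results also hold intervals of medians over genes, from ranked values, and, for the Hbb-bt sets, an interval from resampling cells. Those describe genes or cells of a single sort and not the spread between sorts.

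The gate genes followed the antibodies in most cases. Flt3 RNA stood at 87.7 CPM (84.1 to 91.5) in Flt3+ Ly6d- HSA- cells and 64.1 in Flt3+ HSA+ cells, against 23.8 in Flt3- Ly6d- HSA- cells, 14.2 in Flt3- Ly6d+ cells and 18.02 in the control. Ly6d RNA reached 431 CPM (419 to 444) in the Ly6d+ sort and 415 in the control, but 11.3 to 17.5 CPM in the other 3 sorts. Cd24a, which encodes HSA, stood at 80.4 CPM in Flt3+ Ly6d- HSA- cells, 142 in Flt3+ HSA+ cells, 96.2 in Flt3- Ly6d- HSA- cells, 203 in Flt3- Ly6d+ cells, which were not gated on HSA, and 206 in the control. Kit, the stem cell factor receptor on which every population was gated, lay between 64.9 and 112 CPM. Bcl11b stayed between 0.284 and 3.49 CPM in the 4 gated sorts, against 193 CPM (189.8 to 197) in the control. Il2ra, which encodes CD25 and was gated out of all 4 fractions, was nonetheless detected as RNA, more in each fraction than in the one before: 0.569 CPM (0.311 to 0.954), 2.07 (1.55 to 2.71), 9.20 (7.68 to 10.9) and 30.0 (26.8 to 33.4) in the order given above, and 206 in the control. With every cell thinned to 3000 UMIs, 0.071% of Flt3+ Ly6d- HSA- cells, 0.340% of Flt3+ HSA+ cells, 3.36% of Flt3- Ly6d- HSA- cells, 9.20% of Flt3- Ly6d+ cells and 35.8% of control cells held an Il2ra UMI. In the mm10 build (GENCODE M21), Flt3 lies on chromosome 5 at 147330741 to 147400489, Kit on chromosome 5 at 75574916 to 75656722, Ly6d on chromosome 15 at 74762056 to 74763620, Cd24a on chromosome 10 at 43578284 to 43584265, Il2ra on chromosome 2 at 11642807 to 11693193 and Bcl11b on chromosome 12 at 107910403 to 108003602.

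**Figure D1:**
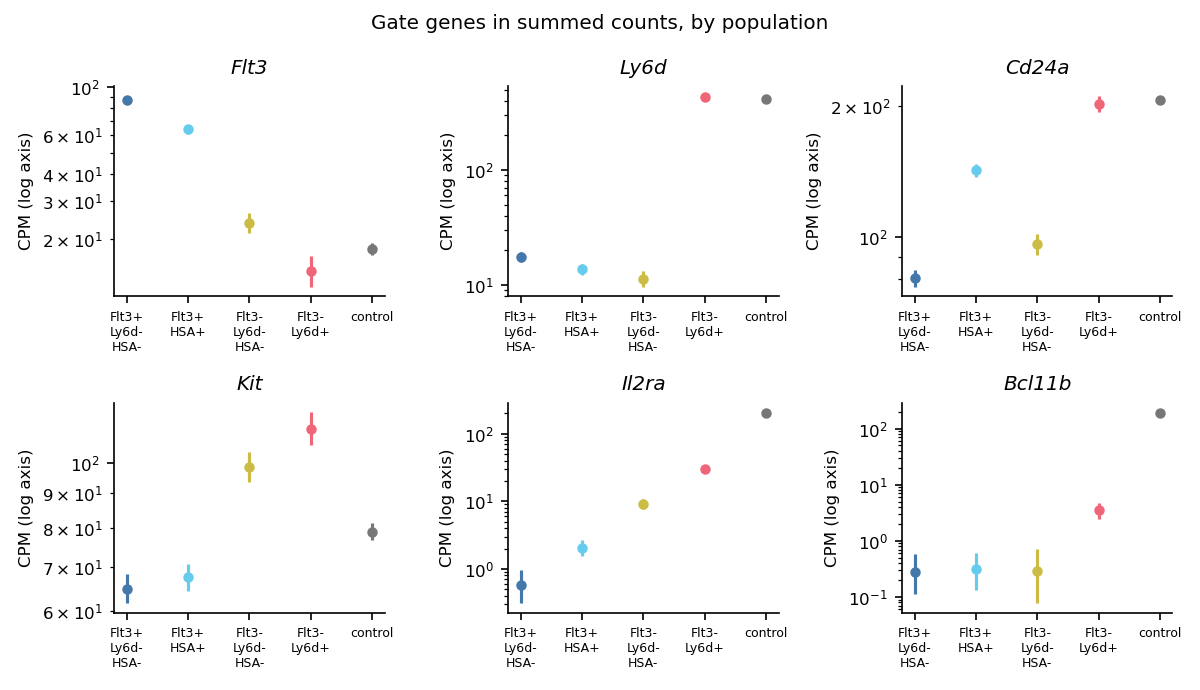
RNA of the 6 gate genes in the 5 sorted populations. The vertical axes are log axes of CPM summed over the cells of each sort (1 sort per population), points are the values and vertical lines 95% Poisson intervals that cover counting error only; Flt3 lies at 87.7 CPM in the first fraction and 14.2 in the last, Il2ra at 0.569 and 30.0, and Bcl11b at 193 CPM in the control.

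The first comparison set Flt3- against Flt3+ cells within the Ly6d- HSA- gate, and asked how the RNA of progenitors without surface Flt3 differs. Tcf7, which encodes TCF-1, the earliest Notch-induced T-lineage transcription factor, was 4.03-fold (3.70 to 4.40) higher in the Flt3- cells, at 122 against 30.2 CPM. Cpa3, a carboxypeptidase of mast cells that early progenitors also express, was 11.5-fold (10.5 to 12.6) higher. In the opposite direction the Flt3- cells held far less RNA of the mitotic machinery: Ube2c, a ubiquitin carrier of the anaphase complex, was 6.39-fold (5.81 to 7.04) lower and the proliferation marker Mki67 was 3.73-fold lower, at 40.9 against 153 CPM. Ccr9, a chemokine receptor that guides progenitors to the thymus, was 7.63-fold (5.94 to 9.96) lower. At least 2-fold apart were 147 genes, 40 higher and 107 lower in Flt3- cells.

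Of the 12 named genes on the lower side, all but Ccr9 belong to the cell cycle. All 21 measured G2 and M phase genes were at least 1.5-fold lower in Flt3- cells, with a median log2 ratio of -1.82, below all 10000 random lists matched in expression, and 14 of 23 S phase genes were lower, with a median of -0.68. Nusap1 and Aspm, spindle proteins, were 6.18-fold and 5.34-fold lower, the mitotic kinases Plk1 and Aurkb 5.07-fold and 4.40-fold, Kif11 and Prc1 4.27-fold and 4.06-fold, and the cyclin Ccna2 4.04-fold. Esco2, Fam64a and Ckap2l were 4.05-fold to 4.82-fold lower. Of S phase genes, Rrm2, a subunit of ribonucleotide reductase, was 2.40-fold and Tyms, thymidylate synthase, 2.20-fold lower. With every cell at 3000 UMIs, at least 5 UMIs of G2 and M phase genes were found in 27.4% of Flt3+ Ly6d- HSA- cells and 7.93% of Flt3- Ly6d- HSA- cells. None of 15 Myc-linked growth genes differed by 1.5-fold, with a median of -0.32. Cells of a granulocyte class, described further on, held 74.0% of the Rrm2 and 50.5% of the Tyms UMIs of the Flt3- Ly6d- HSA- sort. Without them Rrm2 was 6.05-fold and Tyms 3.36-fold lower, and 22 of 23 S phase genes (median -1.05) and 6 of 15 Myc-linked genes, such as Odc1 (1.63-fold) and Srm (1.55-fold), were at least 1.5-fold lower.

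Among 12 measured T-lineage regulators 4 were higher in Flt3- cells and none lower, with a median log2 ratio of 0.36: Tcf7, Zfpm1 (2.83-fold), a cofactor of GATA proteins, Tox (1.90-fold) and Gata3 (1.64-fold). The T-cell receptor and signalling components went the other way or apart, with Cd7 1.92-fold higher, and Thy1 2.47-fold, Rag2 2.64-fold and Dntt, which adds bases to receptor gene junctions, 1.70-fold lower, out of 8 measured. The Notch target Dtx1 was 9.12-fold (5.68 to 15.3) higher and Hes5 1.53-fold lower, and the other 4 of 6 Notch targets lay within 1.5-fold. NK and innate lymphoid markers were higher in 4 of 7 cases, with a median of 1.05: Gzmb 27.0-fold, with 70.7% of its UMIs in the Flt3- sort in 10 cells, the signalling adaptors Fcer1g 2.55-fold and Tyrobp 2.07-fold, and Rora 2.43-fold. Of 17 stem and progenitor regulators, Gata2 (5.27-fold) and Gfi1b (2.003-fold) were higher and Hmga2 (3.32-fold), Hoxa9 (1.98-fold) and Meis1 (1.75-fold) lower, around a median of -0.02. The integrins Itga4 (2.22-fold) and Itgb7 (1.71-fold) were higher, and the chemokine receptors Ccr7 (2.78-fold) and Ccr9 lower, among 14 homing and cytokine receptors. Egr1 (2.77-fold), Fos (1.70-fold), Junb (1.56-fold) and Zfp36 (1.57-fold) were the 4 higher of 10 immediate early genes. Further named genes higher in Flt3- cells were Apoe (6.83-fold), Qrfp (5.27-fold), Muc13 (5.13-fold), the NK receptor Cd160 (4.65-fold), Deptor, an inhibitor of mTOR (4.38-fold), Dhrs3 (3.70-fold), the chemokine Ccl5 (3.59-fold), Scin (3.55-fold), Olfm5 (3.39-fold) and the globin Hbb-bt (6.66-fold).

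Markers of other lineages moved with this contrast. Of 13 granulocyte and monocyte markers 6 were higher in Flt3- cells, such as Cebpa (3.24-fold), Mpo, myeloperoxidase (1.67-fold), and Ctsg, cathepsin G (1.58-fold), while S100a8, with 97.2% of its UMIs in the Flt3+ sort in 10 cells, was 30.2-fold lower, and the list's median was 0.46. All 4 mast cell and basophil markers measured were higher, among them Mcpt8 (3.25-fold), and Cma1, a chymase with 0 UMIs in Flt3+ Ly6d- HSA- cells, had 312 UMIs in 7 of the 1205 Flt3- Ly6d- HSA- cells. The granulocyte class, cells with at least 7 of the 14 markers listed, made up 4.75% of Flt3+ Ly6d- HSA- cells and 8.46% of Flt3- Ly6d- HSA- cells. Without them 7 of the 13 markers were higher and none lower (median 0.76), with S100a8 level (1.01-fold), and 59 genes were higher and 148 lower. Of the 7, Cebpa, Cebpe, Csf3r and Ms4a3 lay under 5 CPM in both sorts, as did S100a8, so these ratios rest on few UMIs. Then 5 of 12 T-lineage regulators (median 0.50) and 5 of 10 immediate early genes were higher, and the G2 and M phase median was -2.15. In the cells without a G2 or M phase UMI among 3000, a choice that takes cycle RNA away, 31 genes were lower. Without all cells that had at least 2 markers of another cell type at full depth, a filter that took out most cells and left 314 and 326, 95 genes were higher and 166 lower.

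**Figure D2:**
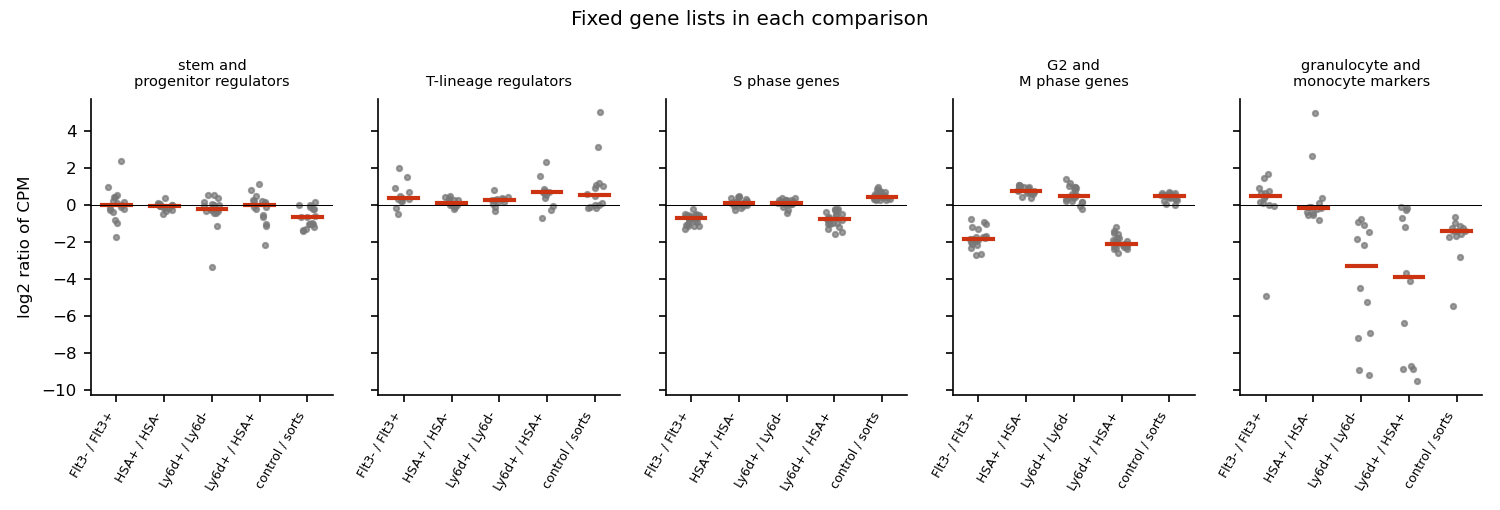
Log2 ratios of CPM for the measured members of 5 gene lists fixed beforehand (columns of panels), in the 5 comparisons along each horizontal axis. Each grey point is a gene at 5 CPM or more in either population and each red bar a list median; G2 and M phase genes lie at medians of -1.82 and -2.11 in the 2 comparisons of Flt3- with Flt3+ sorts, and granulocyte and monocyte markers at -3.31 and -3.88 where the Ly6d+ sort is the numerator.

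The second comparison set HSA+ against HSA- cells among Flt3+ progenitors, and asked which RNA goes with HSA on the surface. The HSA+ cells were richer in mitotic RNA: Ube2c stood at 458 against 214 CPM, a ratio of 2.14 (2.07 to 2.21), and Nusap1 and Kif11 were 2.15-fold and 2.07-fold higher. Spag5, Sgol2a, Hmmr and Cenpl, all of the spindle or centromere, were 2.004-fold to 2.13-fold higher, Mki67 1.93-fold and Top2a, the topoisomerase that untangles chromosomes, 1.87-fold. Lower in HSA+ cells were Ccr9, by 2.82-fold (2.48 to 3.22), and Irf8, a regulator of dendritic and monocyte fate, by 2.79-fold (2.51 to 3.10). By the size rule 9 genes were higher and 5 lower, a count that depends on the weight of deep cells, as given below.

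Of 21 G2 and M phase genes 19 were at least 1.5-fold higher in HSA+ cells (median log2 0.76, above all 10000 random lists), while none of 23 S phase genes was (median 0.13). At least 5 G2 and M phase UMIs among 3000 were found in 51.8% of Flt3+ HSA+ cells and 27.4% of Flt3+ Ly6d- HSA- cells. No member of 12 T-lineage regulators, 8 T-cell receptor and signalling components, 16 stem and progenitor regulators, 5 Notch targets, 15 Myc-linked genes or 10 immediate early genes differed by 1.5-fold. Tcf7 was 1.42-fold and Cd24a itself 1.77-fold higher. Of 14 homing and cytokine receptors Ccr9 and Il6ra (1.52-fold) were lower. Hist1h2bc (2.71-fold), Ms4a6c (2.58-fold) and the chemokine Ccl9 (2.11-fold) were lower too, and Hbb-bt 2.36-fold higher. The 4 antigen presentation genes among 8 dendritic markers, Cd74, H2-Aa, H2-Ab1 and H2-Eb1, were higher, Cd74 by 5.68-fold, but 10 cells held 91.5% of the Cd74 UMIs and 93.8% of the H2-Aa UMIs of the sort. S100a8 and S100a9 were the 2 higher and Cebpa the lower of 13 granulocyte and monocyte markers (median -0.15); they were 6.32-fold and 31.0-fold higher, with 92.5% of S100a8 UMIs in 10 cells and 99.9% of the UMIs of both in the granulocyte class. Cells of that class were 4.75% of HSA- and 2.28% of HSA+ cells and held 83.9% of the Ccl9, 69.9% of the Irf8 and 64.8% of the Ms4a6c UMIs of the HSA- sort. Without them 16 genes were higher and 4 lower, Irf8, Ms4a6c and Ccl9 were no longer 2-fold apart, and Il6ra was 1.18-fold lower. Of the granulocyte and monocyte markers none was then higher and 4 were lower (median -0.30), of which all but Prtn3 lay under 5 CPM in both sorts. With every cell thinned to 3000 UMIs 52 genes were higher in HSA+ cells, with equal weight per cell 51 were, and without the 5% of cells with most UMIs 35 were.

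The third comparison set Ly6d+ against Ly6d- HSA- cells among Flt3- progenitors, and asked which RNA goes with Ly6d on the surface. The Ly6d+ cells were not gated on HSA, and their Cd24a RNA stood at 203 against 96.2 CPM. Differences that go with Ly6d therefore cannot be told apart here from those that go with HSA. Ly6d itself was 38.0-fold (32.4 to 44.8) higher. Fgf3, a fibroblast growth factor, was 5.65-fold (4.22 to 7.68) higher, Il2ra 3.26-fold (2.64 to 4.03), and Il7r, the receptor for interleukin 7, 2.09-fold. Lower in Ly6d+ cells were the primary granule proteases of granulocytes, Elane at 1.41 against 675 CPM and Prtn3 at 9.04 against 1094 CPM, and the myeloid regulator Cebpa, 143-fold (39.3 to 1186) lower on 2 UMIs. By the size rule 13 genes were higher and 33 lower.

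All 12 measured granulocyte and monocyte markers were at least 1.5-fold lower in Ly6d+ cells, with a median log2 ratio of -3.31. Ms4a3 was 573-fold (196 to 2781) lower on 3 UMIs and Hp, haptoglobin, 405-fold (72.4 to 16032) and Igsf6 299-fold (53.4 to 11845) lower on 1 UMI each. Ctsg was 22.0-fold, Ly6c2 68.3-fold, Anxa3 53.3-fold, Cebpe 36.9-fold, Mpo 4.48-fold, and Fkbp11, Ms4a6c and Lbp 4.68-fold to 7.03-fold lower. The granulocyte class made up 8.46% of the Flt3- Ly6d- HSA- cells but 20.4% of their UMIs, against 1 of 847 Flt3- Ly6d+ cells, and its transcripts weigh on every ratio of this pair. Without the class 29 genes were higher and 8 lower in Ly6d+ cells, and 4 of the 12 granulocyte and monocyte markers, Elane, Prtn3, Cebpa and Ms4a3, stayed at least 1.5-fold lower (median -0.43). Of these 4, all but Prtn3 lay under 5 CPM in both sorts. Mpo was then level (1.04-fold), Ctsg 1.49-fold lower and Cebpe, on few UMIs, 3.09-fold higher. In that setting Prtn3 was 2.35-fold lower and Apoe, Egr1, Ctss, Cnrip1, Adgrl4 and Flt3 were 2.95-fold, 2.22-fold, 2.12-fold, 2.05-fold, 2.04-fold and 2.02-fold lower. By that same filter on markers of other cell types, which left 326 and 225 cells, 15 genes were lower and Elane, Prtn3, Ctsg, Ly6c2, Anxa3 and Fkbp11 lay on the other side, at log2 ratios of 0.20 to 1.53. The filter drops cells by granulocyte markers, Elane, Prtn3 and Ctsg among them, so little of this RNA could remain. These turns follow at least in part from that choice.

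Of 21 G2 and M phase genes 8 were higher in the Ly6d+ sort and none lower (median 0.51), such as Nusap1 (2.66-fold), Ube2c (2.28-fold), Kif11 (2.04-fold) and Mki67 (1.93-fold), and Prc1 was 2.14-fold higher. None of 23 S phase genes was (median 0.14). At least 5 G2 and M phase UMIs among 3000 were found in 9.44% (7.54 to 11.6) of Ly6d+ and 7.93% (6.44 to 9.64) of Ly6d- HSA- cells, and these intervals overlap. Without the granulocyte class 16 of 21 G2 and M phase genes (median 1.09) and 9 of 23 S phase genes (median 0.54) were higher, and Rrm2 was 3.30-fold and Aurkb 3.405-fold higher. Of 12 T-lineage regulators Tcf7 alone was at least 1.5-fold higher, at 1.74-fold (1.63 to 1.85), with a list median of 0.29. Without the class Tcf7 was 1.40-fold higher, none of the 12 differed by 1.5-fold and the median was -0.01. Cd247, a chain of the T-cell receptor complex, was 2.08-fold and the recombinase gene Rag2 1.90-fold higher among 8 receptor components (median 0.33). Without the class these 2 were still at least 1.5-fold higher, but the median was 0.06. Hes5 was the higher 1 of 6 Notch targets, with a list median of 0.29, or -0.02 without the class. Of 12 homing and cytokine receptors Il7r and Itga4 (1.67-fold) were higher and Il6ra (1.65-fold) lower. Without the class Itga4 was 1.46-fold higher and Il6ra, most of whose Flt3- Ly6d- HSA- UMIs were in the class, lay on the other side, 1.21-fold higher. The progenitor regulators Lmo2 (2.16-fold) and Gata2 (10.0-fold) were the 2 lower of 17, and Egr1 (1.85-fold), Hspa1a and Hspa1b the 3 lower of 10 immediate early and stress genes. Without the class 3 of the 17 and 5 of the 10 were lower, the latter with a median of -0.61. No Myc-linked gene of 15 differed by 1.5-fold. Cd24a was 2.11-fold, Ccl5 2.78-fold, Hbb-bt 2.91-fold and Cox6a2 2.29-fold higher, Flt3 1.67-fold lower. Mast cell and basophil markers were lower in 3 of 4 cases, among them Mcpt8 (3.68-fold) and Gzmb, and Cma1 had 0 UMIs in Ly6d+ cells. Without the granulocyte class, which held 71.3% of the Mcpt8 UMIs of the Ly6d- HSA- sort, Mcpt8 was 1.32-fold lower and 2 of the 4 were lower. Of 7 NK and innate lymphoid markers Gzmb was the lower 1.

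The fourth comparison set Flt3- Ly6d+ against Flt3+ HSA+ cells and shares no sort with the first. It also crosses the Ly6d and HSA gates, so it is not a contrast of Flt3 alone. Tcf7 was 4.93-fold (4.59 to 5.31) higher in the Flt3- Ly6d+ cells, at 211 against 42.8 CPM. Fgf3 was 39.3-fold (23.3 to 71.2), Il2ra 14.5-fold (10.8 to 19.8) and Cpa3 6.40-fold higher, and Dtx1 18.7-fold. Ube2c was 5.99-fold (5.57 to 6.43) and Mki67 3.72-fold lower, Flt3 4.50-fold and Hmga2, a chromatin protein of fetal and progenitor cells, 4.42-fold. By the size rule 88 genes were higher and 178 lower. Of the genes past the minimum in both comparisons that cross Flt3 (5580), 30 were higher in both and 98 lower in both. No gene past the rule in both went opposite ways. If the calls of both comparisons were independent of each other, 0.396 and 2.80 would be shared. Cell cycle genes were lower together in both, so calls of single genes are not independent. These expected numbers therefore cannot measure how far the overlap exceeds chance.

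Of 12 T-lineage regulators 7 were higher and 1 lower (median 0.68): Tcf7, Zfpm1 (2.97-fold), Patz1 (1.80-fold), Hes1 (1.68-fold), Runx3 (1.63-fold), Gata3 (1.62-fold) and Tox (1.59-fold), with Sox13 1.60-fold lower. All 21 G2 and M phase genes (median -2.11) and 15 of 23 S phase genes (median -0.76) were lower, among them Nusap1, Plk1 and Ccna2 at 4.99-fold to 5.17-fold and Rrm2 at 2.96-fold, and Ckap2l, Sapcd2 and Fam64a were 4.86-fold to 5.27-fold lower. The growth genes Cad and Srm were the 2 lower of 15 Myc-linked genes, and Srm was 1.44-fold lower without the granulocyte class. Cd247 and Cd7 (2.81-fold) were the 2 higher and Thy1 the lower of 8 receptor components, and Dtx1 and Hes1 the 2 higher of 6 Notch targets. NK and innate lymphoid markers were higher in 5 of 7 cases (median 1.30), with Fcer1g at 2.74-fold and Tyrobp at 2.75-fold. Itga4 (2.95-fold), Itgb7 (2.06-fold) and Il7r (1.74-fold) were higher and Ccr9 lower among 12 homing and cytokine receptors. Gfi1b and Nfe2 were higher and Hmga2, Meis1, Hoxa9 and Cd34 (1.58-fold) lower among 16 stem and progenitor regulators, and Junb, Egr1 and Zfp36 were the 3 higher of 10 immediate early genes. Ly6d (31.6-fold), Hbb-bt (8.23-fold), Ccl5 (6.37-fold), the cytokine signalling inhibitor Socs3 (5.68-fold), Dhrs3 (5.28-fold), Qrfp (4.85-fold), Muc13 (3.94-fold) and Cd160 (3.57-fold) were also higher. Ccl5 was level, at a log2 ratio of -0.0238, without cells that had at least 2 markers of another cell type at full depth. That filter left only 225 and 141 cells. Without the granulocyte class alone, Ccl5 stayed 6.05-fold higher.

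Granulocyte and monocyte markers were lower in 9 of 12 cases in the Ly6d+ cells (median -3.88), with Elane at 466-fold, Prtn3 at 81.3-fold, Ctsg at 12.6-fold and Mpo at 2.29-fold, and Anxa3 and Anxa1 were 24.3-fold and 5.21-fold lower. Cells of the granulocyte class were 27 of the 1182 Flt3+ HSA+ cells and 1 of the 847 Ly6d+ cells. Without them 4 of the 12 markers were higher and none lower (median 0.21), Prtn3 lay on the other side, at a log2 ratio of 0.61, Mpo was 1.16-fold higher, and 81 genes were higher and 170 lower. Of the 4 higher markers, Cebpe and S100a9 lay under 5 CPM in both sorts and rest on few UMIs. In the cells without a G2 or M phase UMI 49 genes were lower. The dendritic markers Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ccr9 were the 5 lower and Irf8 (1.86-fold) and Itgax the 2 higher of 9 measured (median -0.84). Most Cd74 and H2-Aa UMIs of the Flt3+ HSA+ sort sat in few cells, as given above. Without cells that had at least 2 markers of another cell type, which left 225 and 141 cells, the median was 0.995.

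The fifth comparison set the control, Kit+ cells sorted without gates on CD25, Bcl11b, Flt3, Ly6d or HSA, against the unweighted mean of the 4 fractions. It held the RNA of committed T-cell precursors: the CD3 chains Cd3g, Cd3d and Cd3e were 330.0-fold (235 to 464), 189-fold and 137-fold higher, Bcl11b 177-fold (135 to 233) and Il2ra 19.7-fold, at 206 against 10.4 CPM. The pre-T-cell receptor chain Ptcra was 38.1-fold, Lef1, a partner of TCF-1 in the same gene family, 32.1-fold and the recombinase gene Rag1 9.95-fold higher. Flt3 was 2.63-fold (2.46 to 2.82) and Lmo2, a regulator of stem and progenitor cells, 2.62-fold lower. By the size rule 56 genes were higher and 35 lower in the control.

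Of 15 T-cell receptor and signalling components 12 were higher and 1, Cd7, 2.05-fold lower, with a median log2 of 2.27: Thy1 (7.03-fold), Cd247 (3.70-fold), Lat (2.80-fold) and Lck (1.63-fold) were among them. Of 14 T-lineage regulators 6 were higher (median 0.53), with Notch3 at 8.74-fold, Ets1 at 2.32-fold, Tcf7 at 2.12-fold, Gata3 at 2.01-fold and Tcf12 at 1.91-fold. Notch3 and Ptcra were the 2 higher of 8 Notch targets. Stem and progenitor regulators were lower in 11 of 17 cases and higher in none (median -0.66), such as Meis1 (2.44-fold), Hmga2 (2.57-fold), Mef2c (2.06-fold), Cd34 (2.05-fold), Hhex (1.58-fold), Spi1, which encodes PU.1 (1.56-fold), and Bcl11a (1.53-fold). Il7r was 4.16-fold higher, with Cxcr4 and Itga4, and Cd44, Il6ra and Il1r1 were lower among 13 homing and cytokine receptors. G2 and M phase genes were higher in 4 of 21 cases (median 0.48), with Mki67 at 1.64-fold, and S phase genes in 7 of 23 (median 0.46), with Rrm2 at 1.97-fold. Cpa3 was 2.66-fold and Ly6d 3.51-fold higher, Ccdc109b 48.4-fold, Fam169b 29.5-fold and Gzma, granzyme A, 17.6-fold. No Myc-linked gene of 15 differed by 1.5-fold, and Zfp36 and Nr4a1 were the 2 lower of 10 immediate early genes. The chemokines Ccl3 (2.96-fold) and Ccl4 (2.80-fold), Ms4a6c (2.91-fold), the Fc receptor Fcgr3 (2.62-fold) and Il12a (2.597-fold) were lower. So were all 13 granulocyte and monocyte markers (median -1.38, or -0.73 without the granulocyte class, which made up 1.33% of control cells), with Prtn3 at 2.94-fold. Without the class 9 of the 13 were lower and 1 higher, 8 of 21 G2 and M phase and 8 of 23 S phase genes and 11 of 15 receptor components were higher, 5 of 13 homing and cytokine receptors and 4 of 10 immediate early genes were lower, and 58 genes were higher and 31 lower. Of the 9 lower markers, Elane, Cebpa, S100a8 and S100a9 lay under 5 CPM on both sides, as did the higher 1, Cebpe.

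Genes at least 2-fold above each of the other 3 fractions at once were counted for each fraction. The Flt3+ Ly6d- HSA- sort had 1, Ccr9, whose smallest ratio was 2.82. The Flt3+ HSA+ sort had 8, among them Cd74 (2.62) and the mitotic genes Nusap1 (2.15), Ube2c (2.14), Spag5 (2.13), Sgol2a (2.07) and Kif11 (2.07), but 50 with every cell thinned to 3000 UMIs, 49 with equal weight per cell, 33 without the 5% of cells with most UMIs and 14 without the granulocyte class. The Flt3- Ly6d- HSA- sort had 5: Apoe (3.53), Cebpa (3.24), Ccl9 (3.23), the basophil protease Mcpt8 (2.87) and Rab44 (2.25), of which the granulocyte class held 89.7% of the Cebpa, 82.1% of the Ccl9, 78.8% of the Rab44 and 71.3% of the Mcpt8 UMIs, and 2 genes of the sort passed the rule without that class. The Flt3- Ly6d+ sort had 5, Ly6d (24.6), Fgf3 (5.65), Il2ra (3.26), Hbb-bt (2.91) and Ccl5 (2.78). Of these, Ccl5 was not above Flt3+ HSA+ cells (log2 ratio -0.0238) without cells that had at least 2 markers of another cell type. That filter took out most cells, and without the granulocyte class alone Ccl5 stayed 6.05-fold above Flt3+ HSA+ cells. Across the 6 pairs of fractions, 14 genes were 2-fold apart between both Flt3+ sorts and 46 between both Flt3- sorts, against 147, 168, 241 and 266 in the 4 pairs that crossed Flt3. The order of both pairs within Flt3 rests on the deepest cells: without the 5% of cells with most UMIs, 35 genes were higher and 5 lower between both Flt3+ sorts and 6 and 10 between both Flt3- sorts.

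Some granulocyte genes sat in few cells, while other markers of the list, such as Lyz2 and Csf1r, were spread over more: cells of every population had a median of 2 of the 14 markers. The class was drawn after the data were seen, at 7 or more of 14 markers, near the low point between cells with few and with many markers. Markers were counted at full depth, which differed between sorts. The class is a range of a score and not a type by itself. It took in 67 of 1412 Flt3+ Ly6d- HSA- cells (4.75%, 3.70 to 5.99), 27 of 1182 Flt3+ HSA+ cells (2.28%, 1.51 to 3.31), 102 of 1205 Flt3- Ly6d- HSA- cells (8.46%, 6.95 to 10.2), 1 of 847 Flt3- Ly6d+ cells (0.118%, 0.00299 to 0.656) and 44 of 3302 control cells (1.33%, 0.970 to 1.78). Of Flt3- Ly6d- HSA- cells 8 had 7 markers and 8 had 6, next to the border. In the Flt3- Ly6d- HSA- sort the class held 99.5% of Elane UMIs, 98.5% of Prtn3 UMIs and 81.6% of Mpo UMIs, but 46.6% of Lyz2 and 34.6% of Csf1r UMIs. T-lineage RNA was low in it: Tcf7 stood at 7.69 CPM in the class and 151 CPM in the other cells of that sort, Dntt at 10.8 and 741, Lck at 4.55 and 196, and Cd7 at 1.05 and 161, whereas Spi1 was higher, at 350 and 211.

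**Figure D3:**
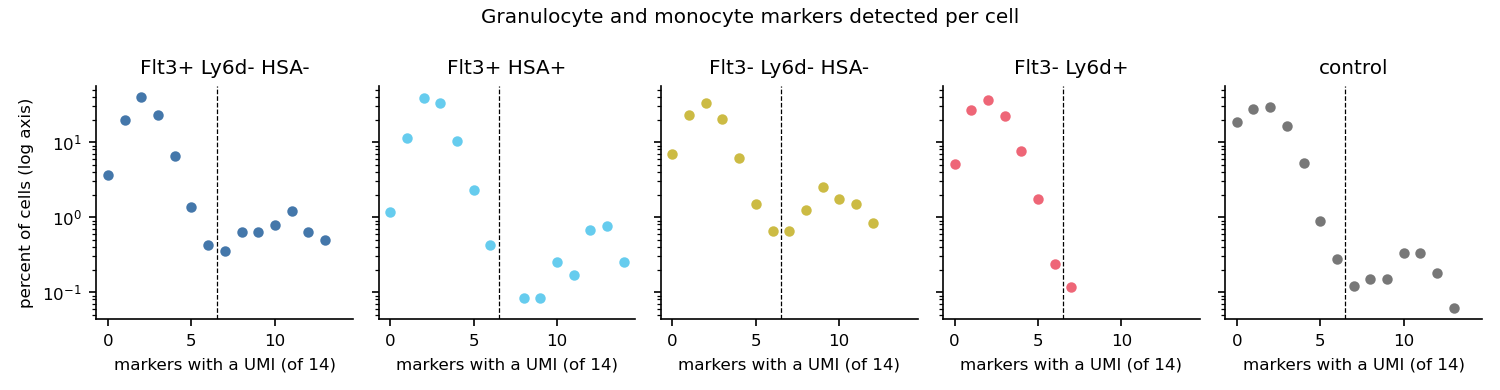
Percent of cells (log axis) of each sorted population by the number of 14 granulocyte and monocyte markers with a UMI in the cell at full depth (horizontal axis). Each point is the share of cells with that number of markers, and the dashed line marks the border of the class at 7; the class holds 8.46% of Flt3- Ly6d- HSA- cells and 0.118% of Flt3- Ly6d+ cells.

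Markers of other cell types were mostly rare. Of 11 B cell markers 1, and of 8 gamma delta T cell markers 2, Blk and Maf, were measured at 5 CPM. Neither Blk nor Maf is a T-cell receptor gene. Low shares for these lists therefore do not show that such cells were rare. With cells at 3000 UMIs, B cell markers (at least 2 with a UMI) were found in 0.085% to 0.484% of cells of the 5 populations, gamma delta T cell markers in 0.121% to 0.517%, thymic epithelial markers in no gated cell and 0.308% of control cells, and mast cell and basophil markers in 0.071% of Flt3+ Ly6d- HSA-, 0.340% of Flt3+ HSA+, 2.41% of Flt3- Ly6d- HSA-, 1.45% of Flt3- Ly6d+ and 1.38% of control cells. Later thymocyte markers were found in 7.11% of control cells and 1.55% to 2.91% of cells of the fractions, and in the control Themis (84.4-fold) and Arpp21 were the 2 higher of 4. NK and innate lymphoid markers were found in 68.9% and 68.2% of cells of both Flt3- sorts, against 44.3% and 42.6% of both Flt3+ sorts and 44.2% of the control. With at least 3 markers the shares were 22.8% and 21.9% in both Flt3- sorts and 8.897% and 6.803% in both Flt3+ sorts. The list holds genes found in every population, such as Tyrobp, at 259 to 739 CPM without the granulocyte class. These are therefore not shares of NK or innate lymphoid cells. Dendritic markers were found in 19.3% to 28.5% and granulocyte and monocyte markers in 15.2% to 34.6% of cells of the 5 populations, shares of at least 2 markers that include genes which progenitors express. No B cell marker was measured at 1.5-fold apart in any comparison. Of the gamma delta markers Maf was lower in the control; without the granulocyte class it was also higher in the first comparison and lower in the third, and Blk too was lower in the control. Epcam was the 1 of 2 thymic epithelial markers higher in the control. Erythroid and megakaryocyte markers were found in at most 1.33% of cells of a population, but Hbb-bt stood at 29.0, 68.4, 193, 563 and 553 CPM in the order of the sorts, and the 66 Flt3- Ly6d+ cells with at least 20 Hbb-bt UMIs held 88.0% of that sort's Hbb-bt UMIs. The cut of 20 UMIs was chosen after the data were seen. Hbb-bs, close in sequence to Hbb-bt, had 1 to 13 UMIs per population, and the alpha globins Hba-a1 and Hba-a2, close in sequence to each other, had 0. How reads that match several genes were counted is not given in the sources used here, so the level of globin RNA is uncertain.

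A score of T-lineage minus progenitor RNA per cell was lowest in Flt3+ Ly6d- HSA- cells and highest in the control. Its median was -0.178 in Flt3+ Ly6d- HSA- cells (SD 0.153 over 1405 cells), -0.162 in Flt3+ HSA+ cells (0.141, 1176 cells), -0.144 in Flt3- Ly6d- HSA- cells (0.167, 1160 cells), -0.0897 in Flt3- Ly6d+ cells (0.159, 826 cells) and 0.00072 in the control (0.298, 3250 cells). The 4 fractions overlapped, with medians closer together than the spread of cells in any of them. At 1500 UMIs per cell the Flt3+ HSA+ and Flt3- Ly6d- HSA- sorts changed places, at -0.102 and -0.105.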

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

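The tests of free RNA and of doublets for the granulocyte genes, the test of free RNA for Hbb-bt, and the settings without granulocyte-class cells and with cells lacking G2 or M phase UMIs were chosen after the result was seen. The cut of 20 Hbb-bt UMIs, used in the test of red blood cell precursors, was set after the data were seen too.

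G2 and M phase genes were lower in both Flt3- sorts than in the Flt3+ sorts, at a median log2 ratio of -1.82 within the Ly6d- HSA- gate. Thinning cannot test depth itself, since ratios of CPM are already scaled for depth and thinning only evens the weight of cells. A larger weight of deep cells is argued against, since the median was -2.04 with every cell thinned to 3000 UMIs. Doublets among the deepest cells are argued against too, since it was also -2.04 without the 5% of cells with most UMIs. Cells of the granulocyte class are argued against as well, with a median of -2.15 without them. Whether Flt3 and cycling go together outside these gates was left undecided by the rule set beforehand, which asked for intervals that do not meet. Among control cells without Il2ra or Bcl11b UMIs, a G2 or M phase UMI was found in 70.5% (61.9 to 78.1) of 132 cells with a Flt3 UMI and 60.2% (57.0 to 63.3) of 952 without, and the intervals meet. The share was higher with a Flt3 UMI, and intervals that meet do not show equal shares. Fewer cycling cells and a slower cycle in the Flt3- sorts would both give less of this RNA; neither was tested, nor was a difference between sorts in handling.

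Cells with 7 or more of the 14 granulocyte and monocyte markers were found in 3 sorts and the control but made up 1 of 847 Ly6d+ cells. Free RNA would give these cells no more of a marker than their depth does; it is argued against, since cells of the Flt3- Ly6d- HSA- sort with 7 or more of the other markers held a median of 4.19 times (2.59 to 4.92, 12 markers) as large a share of a marker as of all UMIs. Cells of another lineage that passed the gates, although these excluded lineage-positive cells, may account for it: T-lineage regulators had a median log2 ratio of -2.74 (-5.03 to -1.34, 12 genes) in these cells over the other cells of the sort. Doublets with a progenitor were first to be judged by depth, and the class did hold 3.10 times the median UMIs of the other cells, as doublets would. A measure chosen afterwards argues against them, since T-lineage regulator UMIs per cell were 0.506 times (0.462 to 0.553) those of the other cells, and Dntt stood at 0.304 UMIs per cell against 7.50.

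Hbb-bt was high in some cells of the Flt3- sorts and the control. Free RNA would reach cells by chance alone. With each Hbb-bt UMI of the Flt3- Ly6d+ sort drawn at random to 1 of 2 sets, it is argued against, since the 63 cells with 10 or more in one set held 9.97 times (8.17 to 12.5) as large a share of the other set as of all UMIs. Red blood cell precursors are argued against, since stem, progenitor and T-lineage regulators had a median log2 ratio of -0.0605 (-0.24 to 0.11, 28 genes) in cells with at least 20 Hbb-bt UMIs over the other cells of the Flt3- Ly6d+ sort. Reads shared between globin copies stay open, with 0 UMIs of Hba-a1 and Hba-a2 in each population, and no biological explanation was tested.

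A few genes went opposite ways, at least 1.5-fold each, in the pair of comparisons of Flt3- with Flt3+ sorts that share no sort, of which the second also crosses the Ly6d and HSA gates. The log2 ratio in the Ly6d+ over HSA+ pair minus that in the Ly6d- HSA- pair was -5.30 for Anxa3, -6.33 for Cebpa, -5.58 for Cebpe, -4.31 for Ctsg, 5.61 for Ly6d and -1.93 for Mpo. These differences were not tested. The granulocyte class held 97.2% of Anxa3, 89.7% of Cebpa, 99.4% of Cebpe, 94.6% of Ctsg and 81.6% of Mpo UMIs of the Flt3- Ly6d- HSA- sort, and Ly6d was itself a gate of the Ly6d+ sort. In data outside the comparisons, 313 unassigned barcodes carried 2 hashtags, and 43.5% of all tag counts matched no hashtag.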

How the results depend on the processing

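The settings without granulocyte-class cells and with cells lacking G2 or M phase UMIs were chosen after the result was seen. Values are in the order of the comparisons. TMM factors, DESeq2 factors and stricter cells moved none of the 14 counts of genes by more than 1.5 times, and the 80% hashtag rule removed no cell and so tests nothing. The score medians moved, from -0.178 to -0.126 in Flt3+ Ly6d- HSA- cells at 1500 UMIs for example, by less than the SD of single cells, a bound too wide to test them. The hashtag check gave 100% both ways. For named genes 957 of 1347 log2 ratios, and 568 of 649 list medians, stayed within their counting intervals or spread, 369 and 75 moved, and 21 and 6 reversed; 84 of 90 shares of cells with other markers moved with depth or the number of markers. The cause of the changes below was not tested, except where fewer cells or a lower or higher minimum admit other genes by construction.

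With a minimum of 5 CPM the genes higher and lower were 102 and 199 in the first comparison, 23 and 11 in the second, 31 and 74 in the third, 204 and 305 in the fourth and 120 and 84 in the control comparison, and 5, 18, 11 and 16 were particular to the 4 sorts. With a minimum of 100 CPM they were 9 and 18, 4 and 0, 3 and 10, 19 and 46, and 15 and 12, with 0, 4, 0 and 2 particular genes. Without cells that had 2 or more markers of another cell type at full depth, which left 314, 141, 326, 225 and 1214 cells and took out mostly cells outside the granulocyte class, they were 95 and 166, 52 and 12, 28 and 15 in the first 3 comparisons and 166 and 123 in the control comparison, and 4, 46 and 2 genes were particular to the first 3 sorts. With totals that leave out mitochondrial and ribosomal protein genes, 62 genes were higher in the first comparison and 58 lower in the control, and 9 and 9 genes were particular to both Flt3- sorts. With equal weight per cell 51 were higher in HSA+ cells, 17 lower in Ly6d+ cells and 49 particular to Flt3+ HSA+ cells. Thinned to 3000 UMIs the same 3 counts were 52, 14 and 50, and 2 genes were particular to Flt3- Ly6d- HSA- cells. Without the 5% of cells with most UMIs 35 were higher in HSA+ cells, 6 higher and 10 lower in Ly6d+ cells and 33 particular to Flt3+ HSA+ cells. With no minimum share of cells 9 genes were particular to Flt3- Ly6d- HSA- cells.

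Without the granulocyte class 16 genes were higher in HSA+ cells, 29 higher and 8 lower in Ly6d+ cells, and 14 and 2 particular to Flt3+ HSA+ and Flt3- Ly6d- HSA- cells. With only cells lacking a G2 or M phase UMI, a choice that by itself takes away calls of cycle genes, 31 genes were lower in the first comparison, 4 higher and 3 lower in the second, 8 and 11 in the third, 49 lower in the fourth, and 0 and 3 particular to both Flt3+ sorts.

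Reversed log2 ratios of the genes named by rule, and of lists, were as follows. With only cells lacking a G2 or M phase UMI, where the turn of Ube2c follows at least in part from that choice, they were 1.27 for Fam64a in the first comparison, -0.50 for Ube2c and -0.17 for Cenpl in the second, -0.58 for Ube2c in the third, and 0.57 for Prtn3, 0.31 for Ctsg and 0.22 for the granulocyte list in the fourth. Without cells with 2 or more such markers they were 0.0344 for Irf8 and 2.06 for Ccl9 in the second, 0.20 for Elane, 0.79 for Prtn3, 1.53 for Ly6c2, 1.53 for Anxa3, 1.20 for Ctsg, 0.79 for Fkbp11 and 0.40 for the granulocyte list in the third, -0.0238 for Ccl5, 2.67 for Ctsg, 1.27 for the granulocyte list and 0.995 for the dendritic list in the fourth, and 0.28 for Prtn3 in the control comparison. That filter drops cells by granulocyte markers, so the turns of granulocyte genes and of their list follow at least in part from it. Without the granulocyte class they were 0.37 for Ly6c2 and 0.12 for Fkbp11 in the third and 0.61 for Prtn3 and 0.21 for the granulocyte list in the fourth. Other list members past 1.5-fold that turned without the class were S100a8 (-0.40) in the second, Il6ra (0.27), Cebpe (1.63), Fcgr3 (0.0911) and Irf8 (0.54) in the third, Mpo (0.22), Cebpe (2.496), S100a8 (0.46), S100a9 (1.20) and Ms4a3 (0.20) in the fourth and Cebpe (1.004) in the control comparison, of which Cebpe, S100a8, S100a9 and Ms4a3 rest on few UMIs. Without the 5% of cells with most UMIs they were 0.22 for Prtn3 and 0.21 for the granulocyte list in the fourth.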

Other observations

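The control sort holds progenitors before and after Bcl11b comes on, and its cells can be split by a Bcl11b UMI, a split chosen after the data were seen. With 3000 UMIs per cell, 928 control cells had a Bcl11b UMI and 2322 did not. In summed counts of the fixed lists, Bcl11b left out, 11 of 16 T-lineage regulators were at least 1.5-fold higher in cells with Bcl11b and none lower (median log2 1.03), 15 of 17 T-cell receptor and signalling components were higher and 1 lower (median 2.29), and none of 16 stem and progenitor regulators was higher and 14 were lower (median -1.73). Among single genes, chosen after the data were seen, Cd3g was found in 36.4% of cells with Bcl11b and 3.402% without, Il2ra in 58.4% and 26.8%, Ly6d in 72.7% and 26.9%, Thy1 in 36.4% and 6.93%, Lat in 63.5% and 26.9%, Il7r in 35.9% and 12.6%, Gata3 in 21.7% and 10.9% and Tcf7 in 58.8% and 38.4%. In the other direction Flt3 was found in 0.108% and 6.24%, Lmo2 in 1.19% and 13.1%, Cd34 in 10.99% and 46.1%, Mef2c in 10.99% and 44.1%, Bcl11a in 11.1% and 34.1%, Spi1 in 14.01% and 34.8% and Kit in 13.9% and 24.98%. Mpo was found in 5.82% and 46.6%, Gzma in 15.1% and 1.59%, Cpa3 in 61.3% and 42.5%, and Hbb-bt and Fgf3 in near equal shares, 18.6% and 19.4%, and 12.1% and 13.0%. A cell without a Bcl11b UMI among 3000 is not shown to lack Bcl11b RNA.

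Unassigned barcodes had a median of 29414 UMIs, 2.004 times the 14680 of assigned cells. In the Flt3- Ly6d+ sort, 10 cells held 28.1% of the Ccl5 UMIs.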
